A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

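The series holds 6 one-colour arrays of Saccharomyces cerevisiae, 3 of the sulfur dioxide-resistant mutant F3 and 3 of its reference strain. Groups and replicate numbers were taken from the sample titles. Per the labels, total RNA was purified with a column kit, 0.2 µg was labelled with Cy3, and cultures were shaken at 150 rpm and 30 °C. The series design states that each culture was grown in triplicate in minimal medium to an OD600 near 1.0, while the growth label describes overnight growth in 100 mL of rich medium, and the latter is taken here as the preculture, which the labels do not state. Replicates are separate cultures by that design text, so p-values set the difference between strains against the spread between cultures of a strain. That spread holds no difference between scan days, since each strain was scanned on its own day.

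Per the file headers, the authors scanned the arrays and extracted spots with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.1. The processed signal of the deposited files is an intensity that the software, per the file headers, had background-subtracted and detrended within each array, with no normalization between arrays. The deposited files also hold the median spot and local background intensity and a flag, set by the software per the file headers, for spots well above background. The authors' deposited table of processed values holds log2 values in which the median of each probe over the arrays is 0. Set against the scanner values centred in the same manner, its columns correlated with r between 0.9877 and 0.9931 and had slopes between 0.9721 and 0.9916, with column medians of 0.0098, 0 and 0.0110 for F3 and −0.0055, −0.0056 and −0.0141 for the reference. The scale is therefore log2 and the direction that of the scanner values, and the scaling between arrays stays unknown.

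The array carries 6256 probes for genes, each spotted 2 times and each for a different systematic name, so no choice between probes of a gene was needed. Control spots were left out, and no gene spot was marked as an outlier. The log2 processed signals of the spots of a probe were averaged and the 75th percentile of the array was subtracted. This scaling assumes that the 75th percentile is the same in both strains, and a difference in total messenger RNA per cell would not be seen. A gene was tested if it was well above background on at least 3 of the 6 arrays, which kept 5948 and left out 308. Names were taken from the RefSeq gene table of the R64 assembly, used only for names, coding lengths and gene order: 5756 systematic names matched by locus tag and 23 by synonym, and 477 kept the name in the files. No coordinates are given, because the sources used here do not name the genome build of the array.

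Differences (F3 minus reference) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the tested genes, threshold 0.05). A second count also required an absolute log2 difference of at least 1. Errors given with ± are the SE of the fit or, where stated, the SD over 3 arrays. For a gene that was not well above background on any array of a strain, the fold is a bound: the mean of the brighter strain against the mean, over the dim strain's arrays, of the higher of the gene's own value and the lowest value among genes well above background. This applied to 40 genes higher and 41 lower in F3. Gene lists (39) were tested with limma's camera at a preset correlation of 0.01, and with an estimated correlation and with fry as alternatives. Beside lists on sulfur, stress, carbon use and growth, these covered nitrogen use, thiamine, drug efflux, iron and copper, cell wall, seripauperins, flocculation, fatty acids, peroxisomes, proton pumps, respiration, histones, mitosis and metal detoxification. Median and mean or test differed in sign in 8 of the lists: sulfite export, sulfur regulators, the pentose phosphate pathway, glycolysis, nitrogen use, cell wall, flocculation and meiosis. List medians with bounded genes set to their bound differed by less than the rounding. Chromosomes, read from the systematic names, were tested as sets in the same manner.

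Genes named in the text were chosen by a rule fixed in advance: the 12 largest increases and the 12 largest decreases among genes with a standard name that were called at least 2-fold without overlap between strains, the 2 largest each way without a standard name, 14 genes of sulfite and stress biology named in advance, and up to 4 members of each called list in its direction, 2 against it, and 3 called members of each other list. Mating-type and marker genes called at least 2-fold were also eligible. The text names only a part of the genes that qualify, 152 in all with those below. The 16 genes outside this rule that the text names were chosen after their values were seen: EHD3, YNR064C, YHB1, NOG1, GLR1, JEN1 and the mitochondrial genes AI1, AI2, AI3, AI5_ALPHA, VAR1, ATP8, COB, COX1, COX2 and COX3.

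The arrays lay on 3 slides. All F3 arrays were on the same slide and scanned on the same day, and the reference arrays were on the other 2 slides and scanned on another day. Each scan day therefore holds a single strain, and no value within a day can be given. The slide, which varies within the reference, was fitted as a random block, with an estimated correlation of 0.0042. In this setting alone, sets were tested with limma's cameraPR on the t statistics of the fit, a different form of the camera test. Alternatives covered background correction (normexp with an offset of 50 on the median spot signal, since the deposited files hold no mean signal), quantile, median and spike-in scaling (the last chosen after seeing the data), the filter on dim probes, the authors' processed values, eBayes with trend and robust options, a replicate block, treat with a log2 limit of 0.5, and leaving out each array. The number of arrays limits the precision: the median SD between arrays was 0.090 for F3 and 0.110 for the reference. The 7 spike-ins used for scaling had SDs of 0.31 to 0.57 over the reference arrays and 0.01 to 0.07 over the F3 arrays. Spike-in scaling therefore adds spread to the reference values, and calls with it are less precise.

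The scripts were tested on simulated data with the means and SDs of the 5948 genes, 3 against 3 arrays and 200 changed genes. Of 100 genes changed 1.5-fold 77 were recovered, of 100 changed 2-fold 94 were recovered, and 3 unchanged genes were called. Of 39 simulated lists of 25 independent genes, the 4 shifted by 0.5 on the log2 scale were called in the right direction and 0 of the others. All genes were drawn independently, few were changed, and the scaling of arrays was not simulated. These rates need not hold for the real arrays, where most genes were called. Figures were drawn with matplotlib 3.10.9.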

Results

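Transcript levels were measured in 2 strains of the budding yeast Saccharomyces cerevisiae: F3, a mutant with resistance to sulfur dioxide that was selected by evolutionary engineering, and its reference strain. Each strain was represented by 3 cultures in early exponential growth in minimal medium, and each culture by 1 one-colour Agilent array. Of the 6256 genes with a probe, between 93.6% and 95.3% were well above background on each array. The 75th percentile of the processed signal was 9517, 9044 and 8303 intensity units on the F3 arrays and 2790, 4905 and 4949 on the reference arrays, and no gene probe was saturated. The software marked the negative control signal as out of range on each F3 array and on no reference array. Its flag for a good spot grid was also unset on each F3 array only, so these quality marks cannot be told apart from strain. All levels below are log2 signal relative to the 75th percentile of the same array, so "rose" and "fell" mean higher or lower in F3 relative to that level. Across the 5948 genes tested, arrays of the same strain correlated with r between 0.9953 and 0.998, and arrays of different strains with r between 0.8595 and 0.8772 (Pearson, across genes, which are not independent replicates).

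The comparison of F3 with the reference asks which genes differ in expression in the resistant strain in the absence of added sulfite. The sulfite pump of the plasma membrane, SSU1 (YPL092W), was 20.4-fold higher in F3: its level was 3.18 ± 0.03 in F3 and −1.17 ± 0.16 in the reference (SD, n = 3 each), a log2 difference of 4.35 ± 0.09 (SE, adjusted p = 6.3e-09). FZF1, the transcription factor known to activate SSU1, was slightly lower in F3 (log2 difference −0.24 ± 0.07 SE, adjusted p = 0.010), and above the reference by 1.47 when arrays were scaled to the spike-in RNAs instead. COM2, another regulator linked to sulfite tolerance, fell by 2.09 on the log2 scale (SE 0.10, adjusted p = 2.1e-07), a call that was lost with spike-in scaling (−0.38, adjusted p = 0.205). As a list of 3, sulfite export and its regulators had 1 member that rose and 2 that fell and was not called by limma's camera test (adjusted p = 0.833), while fry called it higher (adjusted p = 6.4e-04). The plot of SSU1 and its regulators shows these values array by array.

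**Figure D1:**
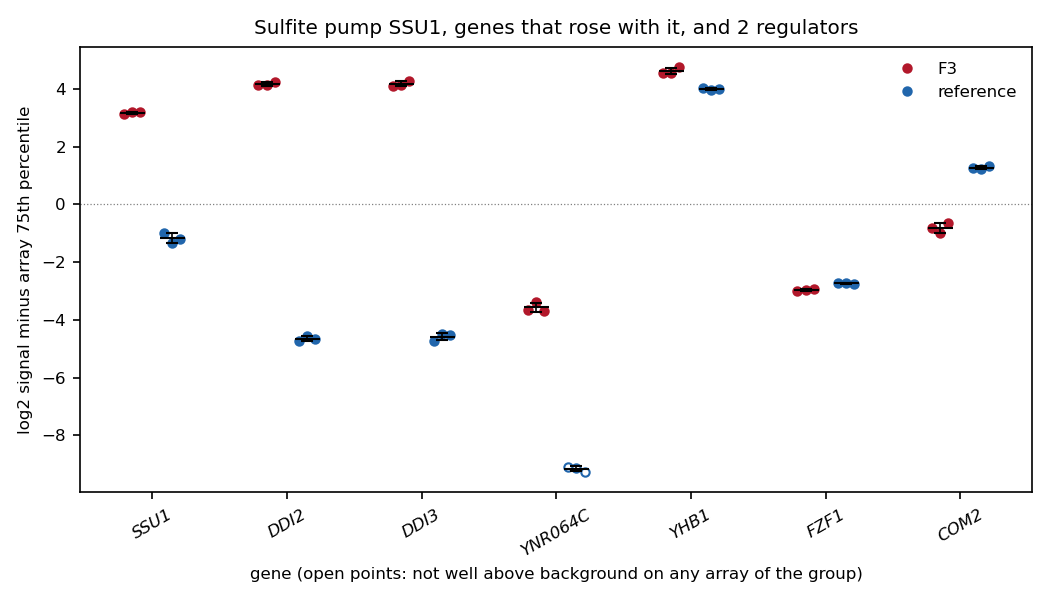
Level of SSU1, of genes that rose in F3 and of the regulators FZF1 and COM2 on each array, as log2 signal minus the 75th percentile of the array (y axis), with points for arrays (3 per strain, open where the gene was well above background on no array of that strain) and bars for the mean ± SD. SSU1 averaged 3.18 in F3 and −1.17 in the reference, while FZF1 averaged −2.97 and −2.73 (with spike-in scaling FZF1 was above the reference).

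DDI2 and DDI3, near-identical genes for cyanamide hydratase, showed the 2 largest increases among genes with a standard name. DDI2 was 453-fold higher in F3 (log2 difference 8.82 ± 0.08 SE, adjusted p = 1.2e-10) and DDI3 was 431-fold higher (8.75 ± 0.09). Their probes may not separate the copies, so the pair is reported as uncertain with respect to which copy rose. The next increases were those of HXK1, a hexokinase that is repressed by glucose (7.40 ± 0.09), MRK1, a kinase related to glycogen synthase kinase (6.73 ± 0.13), CYC7, the minor isoform of cytochrome c (6.70 ± 0.18), and GPH1, glycogen phosphorylase (6.62 ± 0.12). ISF1, HSP26, BDH2, HSP12, TMA10 and HAB1 followed, with log2 differences between 6.07 and 6.43. Of the open reading frames without a standard name, YNL194C rose by 7.73, and YMR206W, not well above background on any reference array, was at least 184-fold higher.

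Among the genes that fell in F3 was ARO3 (YDR035W), which encodes an enzyme that opens the pathway to the aromatic amino acids. It was not well above background on any F3 array and was at least 50.04-fold lower there (level −3.61 ± 0.40 in the reference, SD, n = 3; adjusted p = 1.0e-07). Its neighbour EHD3, which was picked out after the values were seen, was at least 9.56-fold lower and was likewise not well above background in F3. ERG20, the farnesyl diphosphate synthase of sterol synthesis, fell by 6.18 (SE 0.11). PHO84, the high-affinity phosphate transporter (−5.95 ± 0.13 SE), FUI1, the uridine permease (−5.40 ± 0.13), ADH4, an alcohol dehydrogenase (−4.91 ± 0.13), and ZRT1, the high-affinity zinc transporter (−4.46 ± 0.38), fell as well. So did SDA1 (−5.57), DBP2 (−5.49), NSR1 (−5.41) and ALB1 (−4.48), which act in ribosome assembly. The mitochondrial intron reading frame BI2 was at least 64.6-fold lower, and AI5_BETA, another of its kind, fell by 4.46. YAR075W was at least 32.7-fold lower and YGR160W, which overlaps NSR1, at least 14.1-fold lower.

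**Figure D2:**
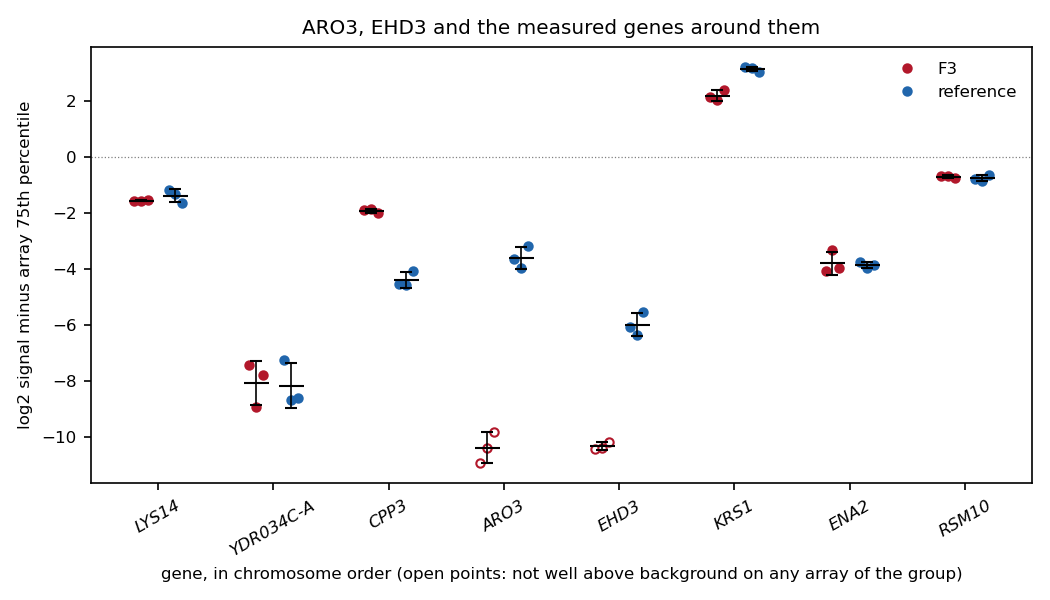
Level of ARO3, EHD3 and the measured protein-coding genes around them, in chromosome order, as log2 signal minus the 75th percentile of the array (y axis), with points for arrays (3 per strain, open where the gene was well above background on no array of that strain) and bars for the mean ± SD. ARO3 averaged −3.61 in the reference and −10.40 in F3, and EHD3 −6.00 and −10.34, whereas each other gene plotted was well above background on at least 1 array of each strain.

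Over the whole genome, limma called 4742 of 5948 tested genes at an adjusted p under 0.05, of which 2467 were higher and 2275 lower in F3 (52.0% higher). At least 2-fold differences were called for 1951 genes (988 higher, 963 lower; 730 and 977 with normexp background correction, 4582 and 164 with spike-in scaling), and at least 8-fold differences for 142 higher and 104 lower genes. The values of the strains did not overlap in 82.4% of the tested genes, where chance gives 10%. Scaled to the spike-in RNAs, 5347 genes were called, 5092 higher and 255 lower (95.2% higher), with a shift of the median of all genes to 1.76 from 0.05, so directions below hold only relative to the 75th percentile. The F3 arrays were scanned together on a different day from the reference arrays, so strain and scan day cannot be told apart by design. The spike-in differences had an SD of 0.222, against 1.33 over genes. This argues against a scan effect that the spike-ins share as the whole cause, but not against effects particular to some transcripts.

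Of the 39 gene lists fixed before the data were examined, 15 were called by limma's camera test with its preset correlation between genes, 8 higher and 7 lower in F3. None of these calls held with an estimated correlation, for which the adjusted p of each list is given beside it. Of the 24 lists that camera did not call, fry, which does not compare a list with other genes, called 17. The number of members that rose or fell was the same when adjusted over the list alone in 34 of the lists, and the other 5 are given where they are described.

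Genes of the general stress response controlled by Msn2 and Msn4 rose throughout: 45 of the 45 tested were higher in F3, also when adjusted over the list alone, with a median log2 difference of 3.16 (adjusted p = 1.3e-15, and adjusted p = 0.563 with an estimated correlation). Besides HXK1, GPH1, HSP26 and HSP12, the list includes TSL1, a subunit of trehalose synthase (5.87 ± 0.09 SE), PGM2, phosphoglucomutase (5.37 ± 0.08), and GLC3, the glycogen branching enzyme (4.52 ± 0.07). The genes of the regulators themselves changed less, MSN4 by 0.81 (SE 0.08) and MSN2 by 0.34 (SE 0.10, adjusted p = 0.012). Protein folding genes controlled by Hsf1 also rose, with 24 of 26 higher, 1 lower and a median of 1.47 (adjusted p = 7.5e-06, and adjusted p = 0.678 with an estimated correlation). HSP78, a mitochondrial chaperone, rose by 3.48 (SE 0.14), the chaperone HSP82 by 3.44 (SE 0.11) and SSA1 by 3.21 (SE 0.10), while SSA3 was the member that fell (−0.60, or 1.11 with spike-in scaling). The proteasome and its regulator Rpn4 had 22 of 33 members higher and 1 lower, with a small median of 0.32 (adjusted p = 0.012, and adjusted p = 0.678 with an estimated correlation). RPN2 and PRE2 rose by 0.90 and 1.00. With spike-in scaling this last list was not called by camera (adjusted p = 0.464). Nor was it called by limma's cameraPR in the fit with the slide as a random block (adjusted p = 0.361). That setting changed both the fit and the form of the list test, so the loss cannot be put down to the slide.

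Genes for the use of sugars and of carbon compounds other than glucose were higher in F3. Among hexose transporters and sensors 16 of 21 rose and 4 fell, with a median of 1.33 (adjusted p = 0.0044, and adjusted p = 0.678 with an estimated correlation). The high-affinity transporters HXT6 and HXT7, whose near-identical sequences leave their separation uncertain, rose by 5.78 (SE 0.10) and 5.59 (SE 0.10), and HXT2 by 4.34 (SE 0.18). MTH1, a negative regulator in glucose sensing, rose by 5.25 (SE 0.08). The low-affinity transporter HXT1 fell (−1.11, or 0.60 with spike-in scaling), as did STD1 (−1.94, not called with spike-in scaling). Of the genes for galactose, maltose and sucrose use 14 of 18 rose and 1 fell, with a median of 1.39 (adjusted p = 4.0e-04, and adjusted p = 0.563 with an estimated correlation). The maltases MAL12 and MAL32, near-identical copies, rose by 5.56 (SE 0.11) and 5.32 (SE 0.13) and the transporter MAL11 by 4.59 (SE 0.07), whereas GAL1 fell (−0.56, or 1.15 with spike-in scaling). Acetaldehyde, acetate and glycerol metabolism had 16 of 21 members higher and 2 lower, with a median of 1.75 (adjusted p = 0.0012, and adjusted p = 0.602 with an estimated correlation). ALD4 and ALD3, aldehyde dehydrogenases, rose by 4.67 (SE 0.14) and 4.42 (SE 0.15), GCY1 by 3.56 (SE 0.08) and GUT2 by 3.24 (SE 0.13). ALD6, the cytosolic enzyme, rose by 1.89 (SE 0.11) and ALD5 fell (−0.67, or 1.04 with spike-in scaling). The TCA and glyoxylate cycles and gluconeogenesis had 26 of 29 members higher and 2 lower, with a median of 1.08 (adjusted p = 1.9e-04, and adjusted p = 0.636 with an estimated correlation). The regulator CAT8 rose by 2.74 (SE 0.14), malate dehydrogenase MDH2 by 2.16 (SE 0.10) and citrate synthase CIT1 by 1.98 (SE 0.08).

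Genes for making ribosomes were lower in F3. All 88 tested ribosome biogenesis genes fell, also when adjusted over the list alone, with a median log2 difference of −2.72 that remained below 0 with spike-in scaling (−1.01). The camera test gave an adjusted p of 2.4e-24, and adjusted p = 0.563 with an estimated correlation. Examples are DBP2, given above, NIP7 (−3.55 ± 0.09 SE) and KRE33 (−3.49 ± 0.09). Ribosomal protein genes followed with a smaller difference: 129 of 138 fell, 1 rose and 8 did not pass, with 130 lower when adjusted over the list alone, and their median of −0.92 lay above 0, at 0.79, with spike-in scaling. Their adjusted p was 2.8e-16, and adjusted p = 0.563 with an estimated correlation. RPS22A fell by 1.59 (SE 0.08) and RPL12A by 1.54 (SE 0.07), both near-identical to a paralog and above 0 with spike-in scaling (0.12 and 0.17), and RPL15B was the member that rose (0.68 ± 0.08 SE).

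**Figure D3:**
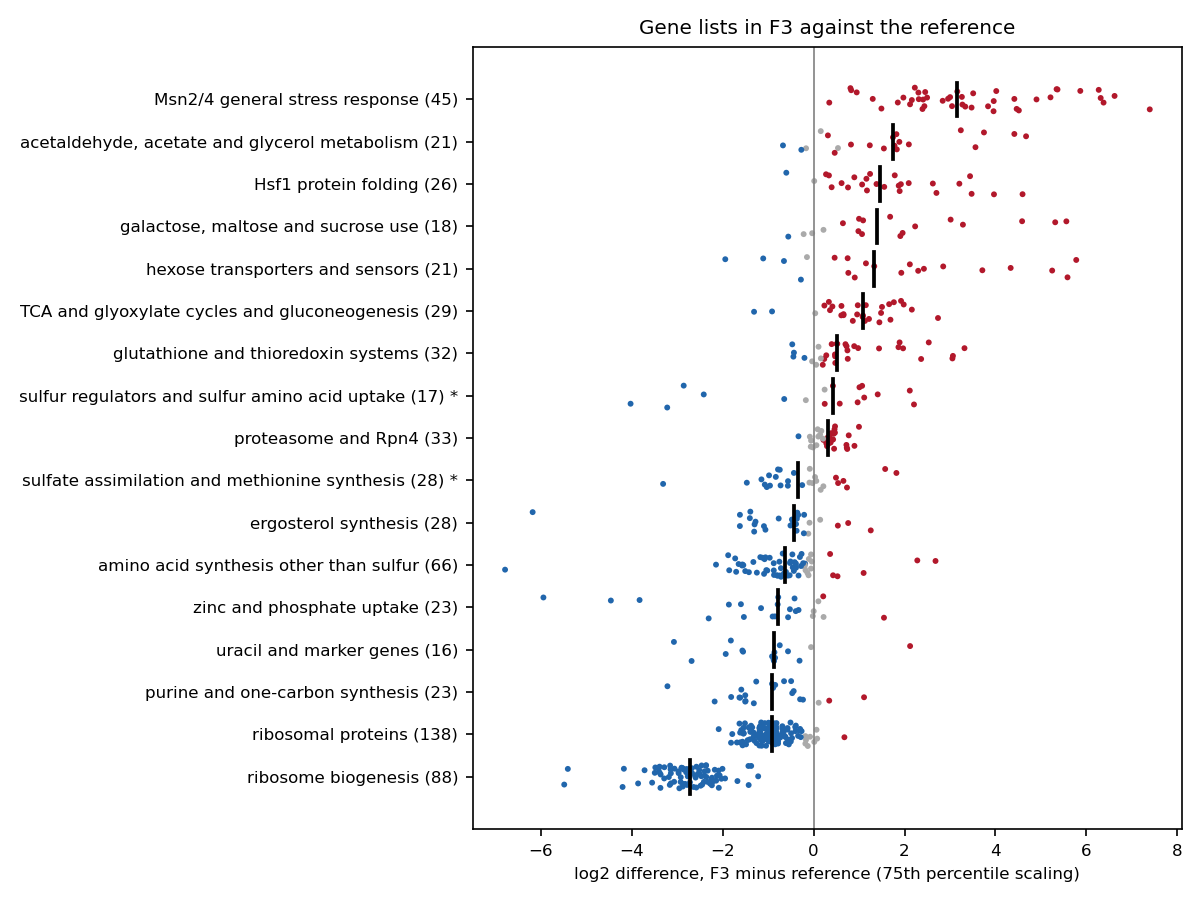
Log2 difference between F3 and the reference for each tested gene of the 15 lists called by camera. Also shown, with a star, are sulfate assimilation and methionine synthesis and the sulfur regulators and sulfur amino acid uptake, which camera did not call. Each gene has a point (red rose, blue fell, grey not called), with black bars for list medians and the count of tested genes in parentheses. Medians run from −2.72 for ribosome biogenesis to 3.16 for the Msn2/4 list, and with spike-in scaling 1 list, ribosome biogenesis, keeps a median below 0.

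Several biosynthetic lists were lower in F3, and each of their medians lay above 0 with spike-in scaling. Amino acid synthesis other than sulfur had 50 of 66 members lower and 6 higher, with a median of −0.63 (1.08 with spike-in scaling; adjusted p = 3.9e-06, and adjusted p = 0.563 with an estimated correlation). The regulator GCN4 fell by 1.86 (SE 0.08, not called with spike-in scaling) and ILV1 by 1.57 (SE 0.08, or 0.14 with spike-in scaling), while GDH3, a glutamate dehydrogenase, rose by 2.68 (SE 0.07). Purine and one-carbon synthesis had 20 of 23 members lower and 2 higher, with a median of −0.91 (0.80 with spike-in scaling; adjusted p = 2.8e-04, and adjusted p = 0.563 with an estimated correlation). IMD4, an IMP dehydrogenase with a close paralog, fell by 3.22 (SE 0.10) and GUA1 by 2.18 (SE 0.11, not called with spike-in scaling). Of the uracil and marker genes 14 of 16 were lower and 1 higher, with a median of −0.88 (0.83 with spike-in scaling; adjusted p = 8.1e-04, and adjusted p = 0.563 with an estimated correlation). URA7 fell by 3.07 (SE 0.16) and URA1 by 2.68 (SE 0.09), and URA10 rose by 2.12 (SE 0.11). Ergosterol synthesis had 22 of 28 members lower and 3 higher, with a median of −0.42 (1.29 with spike-in scaling; adjusted p = 0.0018, and adjusted p = 0.678 with an estimated correlation). After ERG20, its examples MVD1, ERG3 and ERG11 fell by 1.62, 1.39 and 1.31 (0.09, 0.32 and 0.40 with spike-in scaling), and ERG28 rose by 1.26. Zinc and phosphate uptake had 17 of 23 members lower and 2 higher, with a median of −0.78 (0.93 with spike-in scaling; adjusted p = 0.0024, and adjusted p = 0.563 with an estimated correlation). Beside PHO84 and ZRT1, PHM6 fell by 3.83 (SE 0.13), and PHM8 rose by 1.55 (SE 0.13).

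Glutathione and thioredoxin systems were higher in F3, with 24 of 32 members higher, 4 lower and a median of 0.51 (adjusted p = 0.0012, and adjusted p = 0.563 with an estimated correlation). The sulfiredoxin SRX1 rose by 3.32 (SE 0.11), the peroxiredoxin TSA2 by 3.07 (SE 0.11), the glutathione transferase ECM4 by 3.05 (SE 0.10) and the glutaredoxin GRX1 by 2.53 (SE 0.09), while mitochondrial TRX3 fell (−0.45, or 1.27 with spike-in scaling). TRX2 rose by 1.87 (SE 0.11) and the abundant peroxiredoxin TSA1 by 0.72 (SE 0.08). GSH1, the enzyme that starts glutathione synthesis, differed by 0.20 (SE 0.08, adjusted p = 0.041), and this call was lost when any of 5 of the arrays was left out, with normexp background correction and with a replicate block. Of the superoxide, peroxide and Yap1 response 12 of 20 rose and 3 fell, and the list was not called by camera (adjusted p = 0.135), while fry called it higher (adjusted p = 8.5e-04). Its members OYE3 and CTT1 rose by 3.22 and 3.04, and ATR1 fell by 2.50. YAP1 itself differed by 0.10 (SE 0.07, adjusted p = 0.199), and was called with normexp and quantile normalization (0.22, adjusted p = 0.0174) and with spike-in scaling (1.81).

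Sulfate assimilation and methionine synthesis, the route that makes sulfite inside the cell, was not called as a list by camera (adjusted p = 0.217), while fry called it lower (adjusted p = 0.0029): 6 of 28 members rose, 15 fell and 7 did not pass, with a median of −0.34 (1.37 with spike-in scaling). The sulfate permease SUL1 fell by 3.31 (SE 0.24), whereas MET2 and STR3 rose by 1.82 (SE 0.08) and 1.57 (SE 0.10). Of the sulfur regulators and sulfur amino acid uptake genes 10 of 17 rose and 5 fell (median 0.42, mean −0.12, adjusted p = 0.534). At least 2-fold, 6 rose and 4 fell. Among those lower in F3, the permeases SAM3 and MUP1 fell by 4.03 (SE 0.10) and 2.86 (SE 0.13), and SEO1 was at least 3.94-fold lower. The regulator MET4 also fell (−0.65 ± 0.11 SE, or 1.06 with spike-in scaling). The pentose phosphate pathway had 5 of 17 members higher and 9 lower (adjusted p = 0.534): SOL4 and NQM1 rose by 4.47 and 4.06, RKI1 fell by 3.48 (SE 0.13), ZWF1 rose by 0.97 (SE 0.10), and TAL1 differed by −0.07 (SE 0.09, adjusted p = 0.501), or 1.64 with spike-in scaling. Glycolysis and ethanol fermentation had 7 of 28 members higher and 11 lower, 10 of the latter when adjusted over the list alone (adjusted p = 0.914). PDC5 fell by 3.12 (SE 0.27), and PDC1 was lower by the main scaling (−0.68 ± 0.16 SE, adjusted p = 0.0033) but not called with quantile normalization (−0.06, or −0.09 after normexp) or the authors' values (−0.04), and higher with spike-in scaling (1.03).

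Lists on membranes, transport and energy were not called by camera, with members that went both ways. Beta-oxidation and peroxisomes had 17 of 27 higher and 5 lower (median 0.60, adjusted p = 0.0755), with the peroxisomal import factor PEX18 at 2.50 and the thiolase POT1 at 2.34. The respiratory chain and ATP synthase had 21 of 39 higher and 9 lower (median 0.32, adjusted p = 0.193), with COX5B at 3.26 and the NADH dehydrogenase NDE2 at 3.25. Proton pumps had 2 of 18 higher and 12 lower (adjusted p = 0.0960), with PMA2 at −2.25 (not called with spike-in scaling). Fatty acid synthesis had 5 of 24 higher and 11 lower (adjusted p = 0.312), with the desaturase OLE1 at −2.33. Drug and weak acid efflux had 10 of 28 higher and 13 lower (adjusted p = 0.608): RSB1 was at least 18.2-fold higher, ATO2 rose by 4.32 and AQR1 fell by 3.76. Iron and copper uptake had 16 of 36 higher and 13 lower (adjusted p = 0.736), with the mannoprotein FIT2 at 3.46 and TIS11 at 2.86. Arsenic and metal detoxification had 6 of 12 higher and 2 lower, 5 of the former when adjusted over the list alone (adjusted p = 0.534), with CAD1 at 1.41.

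Nutrient, cell surface and cell cycle lists were not called by camera either. Nitrogen use had 11 of 36 higher and 16 lower (adjusted p = 0.451), with the arginase CAR1 at 3.93 and the transporter OPT2 at 4.70. Thiamine synthesis had 10 of 25 higher and 10 lower (adjusted p = 0.914), with THI4 at 1.72. Cell wall and mannoprotein genes had 14 of 41 higher and 12 lower, 13 of the former when adjusted over the list alone (adjusted p = 0.833), with CWP1 at 3.56. Seripauperins and anaerobic mannoproteins had 13 of 30 higher and 6 lower, 12 of the former when adjusted over the list alone (adjusted p = 0.420), with DAN4 at 1.05 and TIR2 at −1.79 (not called with spike-in scaling). Flocculation genes had 2 of 7 higher and 3 lower (adjusted p = 0.833), with FLO11 at 5.23. Histones and S phase had 4 of 25 higher and 13 lower (adjusted p = 0.152), with the cyclin CLN1 at −2.31. Mitosis and M/G1 genes had 4 of 22 higher and 11 lower (adjusted p = 0.193), with AMN1 at −1.84 (not called with spike-in scaling).

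Markers of other cell types that a yeast culture could hold were not called as groups by camera. The a-cell-specific genes had 2 of 8 higher and 4 lower (adjusted p = 0.478). Of those called at least 2-fold, 2 rose and 2 fell. The latter were STE2 at −2.13 (−0.42 and not called with spike-in scaling) and MFA1 at −1.33 (0.38 with spike-in scaling). The alpha-cell-specific genes had 3 of 6 higher and 2 lower (adjusted p = 0.861), with STE3 at 0.80 and MF(ALPHA)1 at −1.40 (0.31 with spike-in scaling). Haploid-specific and mating genes had 9 of 20 higher and 8 lower (adjusted p = 0.833), with PRM2 at 1.67 and FAR1 at −2.29 (not called with spike-in scaling). Meiosis and sporulation genes had 12 of 25 higher and 7 lower (adjusted p = 0.765), and SPO19 was at least 4.99-fold lower.

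Whether whole chromosomes differed was asked because strains from evolutionary engineering can differ in chromosome number. The median log2 difference of the genes on each of the 16 chromosomes lay between −0.10 and 0.20. The camera test called 0 of 16 chromosomes, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.976, while fry, which tests whether the genes of a set move on balance in the same direction, called 12. Over the 32 chromosome arms, medians lay between −0.27 and 0.35 and camera called 0, with 1 at an unadjusted p under 0.05, while fry called 25.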

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

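The net signal of the negative control spots, which no comparison uses, averaged 96.57 (SD 0.822) intensity units on the 3 F3 arrays and 29.05 (SD 2.904) on the 3 reference arrays. It stood out as a signal outside the main measurement that was higher in F3: the scanner software marked it as out of range on each F3 array and on no reference array. The software's flag for a good spot grid was likewise unset on each F3 array and set on each reference array.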

How the results depend on the processing

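Of 2573 values of the 152 named genes under alternatives, 2523 kept direction and side of the threshold, and of 2421 without spike-in scaling, which was chosen after seeing the data, 2400 did. Most of these genes were named for large differences or small adjusted p in the same arrays, and 148 were called in the main fit. These shares therefore say little about genes near the threshold. Leaving out each array gave 4434 to 4651 called genes, 1935 to 2000 at least 2-fold, 15 to 15 lists and 0 to 0 chromosomes; COX3 was at −0.013 without reference replicate 1, and the cause was not tested. Replicate numbers do not pair cultures, and with the number as a block 4595 genes were called. The lists called were 0 with an estimated correlation and 32 with fry, which also called 12 chromosomes. Spike-in scaling gave 4746 genes at least 2-fold. It put above 0 FZF1 (1.47), MET4 (1.06), PDC1 (1.03), TAL1 (1.64), SSA3 (1.11), RPL12A (0.17), RPS22A (0.12), ILV1 (0.14), HXT1 (0.60), GAL1 (1.15), ALD5 (1.04), TRX3 (1.27), MVD1 (0.089), ERG3 (0.32), ERG11 (0.40), MFA1 (0.38), MF(ALPHA)1 (0.31) and AI2 (1.32). The spike-ins averaged −1.71 between strains, which raises every gene by that much. TAL1 was also above 0 with normexp and quantile (0.16), quantile normalization (0.15) and the authors' values (0.17), and the cause was not tested. By fry, sulfite export (median −0.24), glycolysis (−0.10), the pentose phosphate pathway (−0.27) and meiosis (0.27) had the opposite direction from camera; the cause was not tested. Averaging several probes per gene was not run, since each gene has 1 probe. Signal over background limits 40 genes higher and 41 lower in F3 to a bound.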

Other observations

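Transcripts of the mitochondrial genome went both ways: of 17 tested, 6 rose, 8 fell and 3 did not pass, and those named here, except BI2 and AI5_BETA, were chosen after their values were seen. Of 6 intron reading frames 4 fell, 1 rose and 1 did not pass. The intron reading frames AI1 (−4.41 ± 0.29 SE) and AI3 (at least 7.62-fold lower) fell with BI2 and AI5_BETA, while AI5_ALPHA rose by 0.59 (adjusted p = 0.0149, a call lost without reference replicate 1 or 2) and AI2 was at −0.39 (adjusted p = 0.110). Lower in F3 were also VAR1, a protein of the mitochondrial ribosome (−3.02 ± 0.26 SE), and ATP8, a subunit of the ATP synthase (−2.43 ± 0.32). Reference values of BI2, AI1, VAR1 and ATP8 were widely spread, with SDs of 0.81, 0.69, 0.63 and 0.77. Each was highest in reference replicate 3, which lay alone on its slide, and the F3 values did not overlap with the reference. Of the 4 respiratory chain subunits, COB, COX1 and COX2 rose by 1.22, 1.13 and 1.21, and COX3 did not pass (0.17, adjusted p = 0.357).

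F3 replicate 2 stood apart in some genes. The copper transporter CTR3 was at −4.47, −1.04 and −4.76 in the F3 cultures, INO1, which makes inositol phosphate, at 1.86, −0.91 and 1.94, and the flocculin FLO11 at −0.33, 1.31 and −0.12. Without that culture their log2 differences were 1.82, 5.09 and 4.72, against 3.01, 4.16 and 5.23 with it. The call of CTR3 was lost with normexp and the 75th percentile (adjusted p = 0.060) and with the trend and robust options of eBayes (adjusted p = 0.062).

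The tests on glucose-repressed genes, on the genes beside SSU1 and on the other amino acid genes were chosen only after the result was seen. The rise of the Msn2/4 list and the fall of ribosome biogenesis were set against several explanations. A labelling or scanning effect that the spike-ins share is excluded as the whole cause. Differences of the 7 spike-ins lay between −2.05 and −1.40, with an SD of 0.222, or 0.168 of the SD over genes. These few RNAs cannot show an effect particular to some transcripts, and they do not see harvest or extraction. Removing the trend with signal level and coding length left medians of 3.25 and −2.70, so that trend is not the whole cause. Less glucose left in the F3 cultures at harvest could give the pattern, and strongly glucose-repressed genes had a median of 1.58, with 7 of 8 higher, among them JEN1 at 3.75. Strain and culture state cannot be separated here, so this stays open.

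SSU1 rose together with DDI2, DDI3 and YNR064C, which was at least 42.1-fold higher. Higher activity of Fzf1 could link them. Its reported target YHB1 was called higher as well, by 0.62 (SE 0.08, adjusted p = 1.1e-04 by limma), or 1.54-fold. Spike-in scaling raises this value, as it does for every gene. This leaves the link through Fzf1 undecided. Extra copies of the SSU1 region are excluded as the whole cause, since DDI2, DDI3 and YNR064C lie on other chromosomes. The 4 measured genes beside SSU1, from NOG1 at −3.72 to GLR1 at 0.74, had a median of −1.21 (0.50 with spike-in scaling), which lies 5.56 below SSU1 under either scaling (SD of the 4 genes 1.87), although 2 of them belong to ribosome lists that fell. Extra copies of SSU1 alone were not tested.

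ARO3 was well above background on 0 F3 arrays, while both flanking genes were so on 3, and ARO3 and EHD3 were the 1 adjacent pair among the 14 genes silent in this manner (of 41) that have a place in the gene order used. Lost or altered sequence at the locus stays open, since ARO3 was singled out for its fall and expression alone cannot tell lost sequence from silencing. A fall of amino acid synthesis as a group is excluded as the whole cause, since its other genes had a median of −0.61. Both ARO3 spots were low on all 3 F3 arrays, so a defect of a single spot or array is not the whole cause. The spots read at most 12.46 intensity units there and at least 189.5 on the reference arrays. ARO3 was named for a fall without overlap between strains, and the F3 arrays shared a slide. A fault of the probe common to that slide therefore stays open. The 2 spots differed by at most 0.90 on an F3 array, which says little for spots at background.

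There are 10 splits of the arrays into 3 and 3, too few for a share under 0.05. Every split but the real one mixes both strains in each group, so none shows what chance alone gives. Mixed groups have a wide spread within and still differ in part by strain. The counts below therefore neither back nor weaken the calls. As large a result as the real one came in 1 split for called genes (4742, highest other 0), in 1 for genes at least 2-fold (1951, highest other 0), in 7 for lists (15, highest other 19) and in 10 for chromosomes (0, highest other 0).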
